A study of Drosophila melanogaster with 14 samples.

How the data were processed

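Total RNA depleted of ribosomal RNA was sequenced from BG3 cells with Ion Total RNA-seq chemistry, per the labels' protocols. The labels place 6 libraries in the Mock group, 3 in Ph, 3 in Sce and 2 in Pc. RNA interference used double-stranded RNA added to the medium, with a pair of fragments per target, and the targets are reported there as knocked down, per the labels' protocols. The labels number the replicates but do not say that they came from separate cultures or that a number marks a shared day, so any p-value measures only the spread between these libraries, which may be technical. Whether the counting used strand is not given in the sources used here, and reads of overlapping or antisense genes may therefore not be told apart.

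The values came from 1 table of 7624 genes, in which per the file headers the authors gave the mean signal of each group, the ratio of each treated group to Mock, a p-value and a q-value. The submitters' processing notes name bedtools, without a version or a role; the aligner, the genome build, the annotation, the normalization and the test are not given in the sources used here. The deposited signal columns share a common total, the largest sum exceeding the smallest by 0.021%, so the values had been scaled. Whether single libraries or group means were scaled, and whether the authors divided by gene length, is not given. Every deposited ratio equalled the quotient of the authors' means within 2% or 0.001. The authors' p-values and q-values are given to 3 decimals, and a value of 0.000 is below what those decimals resolve. The deposited q-value had a median of 0.594 (Ph), 0.617 (Sce) and 0.682 (Pc) times the Benjamini-Hochberg value of the rounded p-values. Every listed gene had a highest group mean of at least 798.3, and 76 had one under 900, so genes with low signal in all groups were left out upstream. The lowest value of a column was shared by 20 genes in Mock (1.40), 4 in Ph (1.48), 5 in Sce (0.77) and 12 in Pc (0.65), and is read as no signal. No fold is given against it.

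The table held 0 columns of values per library. The tests chosen before the data were examined needed such values, as did the gene set tests, and were therefore replaced by the fallback chosen with them, which was values and folds without a test. Genes were called at the authors' q-value under 0.05, and no p-value was computed here. Because the depth of each library is unknown, no interval or limit of detection is given. A second set of deposited columns is marked nt.gene in the header, and neither the header nor the labels say what was measured. Its 3 columns of means match no labelled sample and were not used here; its ratios, p-values and q-values for Sce and Ph against Mock are kept apart from the comparisons, and its log2 ratios come from the deposited ratios without a pseudocount.

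Folds were taken as the ratio of means, and log2 ratios with a pseudocount of 1. The 33 gene lists of complexes, pathways, cell types and housekeeping functions were fixed before the data were examined, and 30 of them had listed genes. The lists of fat body and gut genes, mitochondrially encoded genes and small nucleolar and Cajal body RNAs had 0 listed genes; the name pattern of the last had also taken 4 protein-coding genes (scaf, scaf6, scat and sno), which were left out after the data were seen. Several lists overlap in what BG3 cells express, and markers of other cell types were included among them. For each list the genes with q under 0.05 were counted, the authors' rounded p-values were also adjusted by the Benjamini-Hochberg method over the list alone, and the percentile of the list's median log2 ratio was taken among 10000 random lists of equal size matched on mean level in 20 bins. These percentiles describe these means and are not tests, since genes are not independent replicates. The random lists were not matched on exonic length, except in a separate comparison of ribosomal protein and histone genes with Ph. Genes low in every group are absent from the table, so medians of lists without signal in Mock are conditioned on the outcome. Level was judged by the mean over the 4 groups, and 3812 genes lay at or above its median. Since that mean includes the labelled groups, a gene may reach the median through its own rise.

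The genes named were fixed by rule before the data were examined: the targeted genes, the 10 largest folds in each direction at or above the median mean level (5 where labelled groups are set against one another), Polycomb group and Hox genes, and up to 4 members of each list with the smallest q-value. Genes known only by a CG or CR number and small RNA genes were left out of the largest folds. Some genes that meet this rule are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

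For comparisons that share Mock, 100 sets without any effect were simulated with the group sizes of the labels and independent noise of 1 spread for every gene and group. The covariance that the shared Mock gives was estimated from the spread of the difference between labelled groups, as if that spread were all noise. It is therefore an upper estimate where libraries of all groups have an equal spread and noise is independent between genes. The smallest over the pairs was used for each. The overlap expected of independent lists is the product of their sizes divided by 7624, which leaves out the condition on what is listed. Exonic lengths came from Ensembl release 115, matched for 98.6% of genes through current and older symbols. The order of neighbouring genes came from the RefSeq gene table of release 6 of the genome, where 7517 symbols matched 1 gene. Since the authors' build is not given, no coordinates are printed.

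Alternatives were pseudocounts of 0.1 and 10, rescaling by the median ratio, quantile normalization, and only genes at or above the median mean level. Chosen after seeing the data were q-value thresholds of 0.1 and 0.01, Benjamini-Hochberg values recomputed from the rounded p-values (0.000 taken as 0.0005), leaving out the targeted genes, and gene lists and neighbours limited to the 7261 genes whose Mock mean alone was at least 798.3, matched on the Mock mean in 20 bins. Rescaling was applied to group means. The steps were tested on simulated data for Ph against Mock: of 200 genes changed 4-fold among 7624, 100% were recovered at 2-fold, with 0 unchanged genes past it. The changed genes all lay at or above the median mean level, and every gene had the same small spread. These settings nearly fixed the outcome, so it checks the steps and not the error rate in the real data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.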

Results

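RNA was measured in BG3 cells (ML-DmBG3-c2), a Drosophila cell line derived from the larval central nervous system, after RNA interference against 3 kinds of subunit of Polycomb Repressive Complex 1 (PRC1). PRC1 holds Polyhomeotic (Ph, encoded by the near-identical neighbouring genes ph-p and ph-d), Sex combs extra (Sce, which ubiquitinates histone H2A) and Polycomb (Pc, which binds trimethylated lysine of histone H3). There were 14 total RNA libraries, of which 6 came from mock-treated cells (Mock), 3 from cells treated against Ph, 3 against Sce and 2 against Pc. The values were the authors' mean signal per gene and group for 7624 genes, with the authors' ratio to Mock, p-value and q-value. A gene is said here to have risen or fallen only where the q-value was under 0.05. Values of single libraries were not used here, so no spread between replicates stands beside the means, and the depth of each library is unknown. The largest of the 4 column sums of group means exceeded the smallest by 0.021%, so the groups were on a common total.

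The RNA of each targeted gene was examined first, as a check of the labels, and it stood above Mock in its own group in every case. For ph-p the authors' mean was 22215 in Mock and 191903 in the group treated against Ph, and for ph-d it was 24093 and 194873. The ratios of this pair in the authors' deposited table were 8.64 (q = 0.017) and 8.09 (q = 0.028), although reads of such similar genes may have been divided between them. Sce stood at 25261 in Mock and 681672 in its own group, a ratio of 27.0 in the authors' deposited table with p = 0.008 and q = 0.198. Pc stood at 6367 and 136729, a ratio of 21.5 in the authors' deposited table with p = 0.015 and q = 0.13. In the 8 pairings of a targeted gene with a group treated against another subunit, the ratios in the authors' deposited table lay between 0.876 and 1.45. The RNA signal therefore does not show the labelled depletion in any of the 3 groups, and the differences of Sce and Pc did not pass. Reads from the added double-stranded RNA were not told apart from those of the genes. This signal thus does not decide whether depletion took place. The groups are called the groups labelled Ph, Sce and Pc throughout. Every direction given for them is that of the labelled group against Mock.

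Among the other PRC1 genes, the ring finger genes Psc and Su(z)2 stood higher in each labelled group. Psc rose in all 3, with ratios in the authors' deposited table of 3.24 (Ph, q = 0.029), 2.78 (Sce, q = 0.045) and 2.51 (Pc, q = 0.033). Su(z)2 rose in the groups labelled Sce and Pc, with ratios in the authors' deposited table of 5.81 (q = 0.005) and 6.49 (q = 0.002), and its ratio was 5.24 in the group labelled Ph (q = 0.062). Scm, Kdm2 and l(3)73Ah had ratios between 0.86 and 1.38 in the authors' deposited table, and their q-values there were 0.339 or more. Of the 9 listed PRC1 genes, 3 rose in the group labelled Ph, but ph-p and ph-d among them were targeted there; in each of Sce and Pc, Psc and Su(z)2 were the 2 that rose. Adjusted over the list alone, the counts were 5, 3 and 3, and include the genes targeted in the group.

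**Figure D1:**
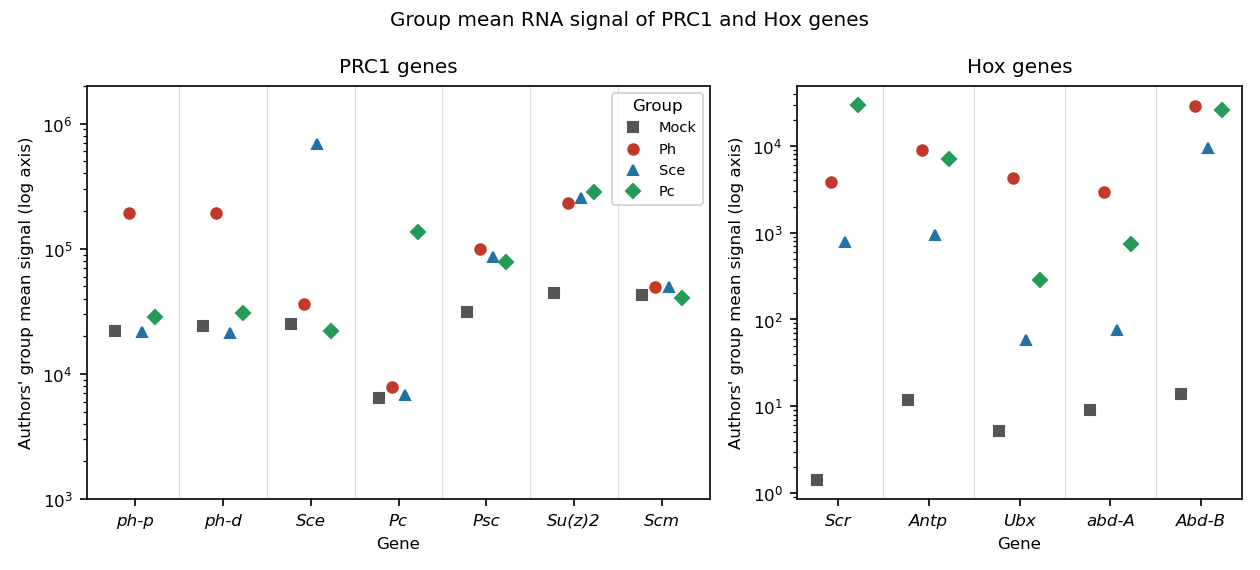
The authors' group means (signal units, log axis) of PRC1 genes on the left and of the 5 listed Hox genes on the right, with 1 point per group and no error bars because values per library were not used. Each targeted gene is highest in its own labelled group (ph-p 191903, Sce 681672, Pc 136729), and the Hox genes lie at or under 13.7 in Mock.

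The comparison of the group labelled Ph with Mock asks which transcripts differ when this subunit is targeted. Hox genes, the homeobox genes that set segment identity, were among the largest differences. Of the 8 Hox genes on the list, 5 were listed in the table, and Scr, Antp, Ubx and Abd-B rose. The authors' mean of Abd-B went from 13.7 in Mock to 28606, that of Antp from 11.8 to 8938 and that of Ubx from 5.18 to 4261, with q-values in the authors' deposited table of 0.007, 0.022 and 0.014. Scr was listed at the column's minimum of 1.40 in Mock, so no fold is given, and at 3796 in the labelled group (q = 0.005 in the authors' deposited table). The authors' mean of abd-A was 9.16 in Mock and 2937 in the labelled group, with q = 0.087 in the authors' deposited table. Adjusted over the list alone, all 5 passed. These genes have almost no signal in Mock, so their folds are imprecise and the means are given instead.

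Other developmental regulators followed. Of 61 such genes fixed as Polycomb targets (homeobox, T-box, paired-box, zinc finger and other factors) 27 were listed in the table, of which 17 rose and 1 fell (20 and 2 adjusted over the list alone), with a median log2 ratio of 5.25. Optix, which acts in eye development, rose from an authors' mean of 32.4 to 21557, the spalt gene salr from 108 to 13807 and the gut patterning gene drm from 14.4 to 2312, each with a q-value of 0.000 at 3 decimals in the authors' deposited table. The zinc finger homeobox gene zfh2 rose 21.0-fold (q = 0.001) in the authors' deposited table. The member that fell was C15, a homeobox gene of leg patterning, at 0.094 of Mock (q = 0.011) in the authors' deposited table. Of 24 segmentation and head gap genes 9 were listed, of which 4 rose and 0 fell. The head gene oc went from an authors' mean of 9.53 to 25732 (q = 0.003 in the authors' deposited table), btd from 65.2 to 1064 (q = 0.015 in the same authors' deposited table) and cad from 32.7 to 838 (q = 0.024, also in the authors' deposited table). The engrailed paralog inv rose 3.03-fold (q = 0.043) in the authors' deposited table. Each of these 3 lists, Hox genes included, had a median above that of all 10000 random lists of equal size matched on mean level (percentile 100). These medians are conditioned on the rise itself, because genes low in every group are absent from the table and a gene without signal in Mock is listed only where a labelled group is high. In an analysis chosen after the data were seen, lists were limited to genes whose Mock mean alone was at least 798.3, the lowest level listed, and matched on the Mock mean. No Hox gene was left. Of the 27 developmental regulators 10 were left, with medians of 0.13 (Ph, percentile 60.0), 0.26 (Sce, 84.5) and -0.08 (Pc, 21.5), so the list as a whole did not stand out there. The 3 segmentation genes left had a median of 1.33 with Ph (percentile 99.3). The same condition bears on every list with members low in Mock.

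Ligands and targets of several signalling pathways rose in part. Among 17 listed genes of the Wnt, Hedgehog and Dpp pathways, 3 rose, namely wg (21.9-fold, q = 0.009), Wnt4 (18.2-fold, q = 0.03) and the Dpp antagonist Dad (5.95-fold, q = 0.016) in the authors' deposited table, and the list's median lay at percentile 26.2. Of 16 listed Notch pathway genes 6 rose (9 adjusted over the list alone; median log2 ratio 1.34, percentile 100); of the 12 listed by their Mock mean alone 4 rose, with a median of 0.61 (percentile 99.99). Those that rose included the Enhancer of split genes HLHm3 at 19.9-fold (q = 0.01) and HLHmbeta at 7.65-fold (q = 0.003), and the glycosyltransferase gene fng at 2.92-fold (q = 0.009), in the authors' deposited table. Of 15 listed genes of EGF receptor and FGF signalling 3 rose (9 adjusted over the list alone, median log2 ratio 0.99, percentile 100). These were the secreted inhibitor aos at 8.73-fold (q = 0.043), the FGF receptor htl at 2.01-fold (q = 0.046) and edl at 1.98-fold (q = 0.04) in the authors' deposited table. The protease gene rho, which releases EGF receptor ligands, had a ratio of 10.9 with q = 0.155 in the authors' deposited table. Of 11 JAK-STAT genes chinmo alone passed, with an authors' mean of 71.0 in Mock and 27161 in the labelled group (q = 0.011 in the authors' deposited table; list percentile 99.3). Of 15 ecdysone response genes ImpE1 passed, with an authors' mean of 60.5 in Mock and 4831 in the labelled group (q = 0.002 in the authors' deposited table; list percentile 39.8).

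Markers of cell types moved unevenly. The glial transcription factor repo had the largest fold among named genes at or above the median mean level, 54.0 in the authors' deposited table (q = 0.004). Its authors' mean was 2567 in Mock, where the median over genes was 20404, and 138658 with Ph. The mean level includes the labelled groups, so its rise itself bears on its place there. Of 13 listed glial genes, axo, Nrg and nrv2 also rose, at 60.2-fold (q = 0.04), 3.06-fold (q = 0.028) and 2.10-fold (q = 0.015) in the authors' deposited table, while wun2 fell to 0.156 (q = 0.042) in the authors' deposited table; the list's median lay at percentile 87.9. Of 6 neural precursor genes, pros (29.3-fold, q = 0.023 in the authors' deposited table) and SoxN rose, the latter from an authors' mean of 35.0 to 19970 with q = 0.041 in the authors' deposited table (list percentile 99.89). Ace was the gene that rose among 7 neuron genes, from an authors' mean of 61.4 to 1391 (q = 0.027 in the authors' deposited table; list percentile 78.8), and twi among 8 muscle genes (30.1-fold, q = 0.03 in the authors' deposited table; list percentile 69.8). None of 13 hemocyte genes or 11 immune genes passed at q under 0.05 in the authors' deposited table, with list medians at percentiles 2.74 and 66.3. Of 22 axon guidance and adhesion genes, Fas2 rose (5.56-fold, q = 0.003) and the netrin gene NetA fell (0.348, q = 0.03) in the authors' deposited table, with the list's median at percentile 4.07. Adjusted over the list alone, the counts were 5 higher and 1 lower for the Wnt, Hedgehog and Dpp list and 1 higher and 2 lower for axon guidance and adhesion, and those of the other lists named here without such a count did not differ.

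The rule for named genes took the 10 largest folds in each direction at or above the median mean level. After repo, the highest were the adhesion gene Ama (33.0, q = 0.127), the receptor kinase gene sev (27.0, q = 0.009), zfh2, the filamin gene cher (14.01, q = 0.028) and Argk (11.3, q = 0.086) in the authors' deposited table. They were followed by rho, the titin-related gene zormin (9.33, q = 0.004), aos and the glutamate receptor interacting protein gene Grip (8.69, q = 0.000) in the authors' deposited table. The lowest were C15, wun2, the GABA receptor gene GABA-B-R3 (0.162, q = 0.03), the lipophorin receptor gene LpR1 (0.193, q = 0.374) and wun (0.251, q = 0.135) in the authors' deposited table. They were followed by shf (0.264, q = 0.063), Fili (0.267, q = 0.043), RpS14a (0.28, q = 0.13) and His4r (0.284, q = 0.191) in the authors' deposited table.

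In all, 296 of 7624 genes passed in the group labelled Ph, of which 268 rose and 28 fell; at an unadjusted p under 0.05 the authors' deposited table holds 1059 higher and 358 lower. The median ratio was 3.26 among those that rose and 0.388 among those that fell. Genes already active in Mock were among them: 182 of the 268 had a Mock mean of at least 798.3, the lowest value that the highest group mean of any listed gene took. Of the other 86, 44 had a Mock mean under 100. Of the 3812 genes at or above the median mean level, 131 rose, with a median ratio of 1.82, and 12 fell; of the rest, 137 rose and 16 fell. The share that passed was 3.75% in the former and 4.01% in the latter. By size alone, without a test, 502 genes were at least 2-fold higher than Mock and 503 lower, so the excess of higher genes holds for the calls and not for the folds. The call rests on the authors' q-values, whose test is not given in the sources used here.

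Genes of the translation machinery stood lower without passing. Of 86 cytosolic ribosomal protein genes 0 passed at q under 0.05 in the authors' deposited table, and 80 had a ratio under 1. Their median log2 ratio was -0.78, under all 10000 matched random lists (percentile 0.0). For RpS6 and RpLP2 the ratios in the authors' deposited table were 0.457 (q = 0.058) and 0.44 (q = 0.092). All 96 copies of replication-dependent histone genes had a ratio under 1 (median log2 ratio -1.06), and 3 of them, among them His3:CG33863 (0.35, q = 0.021 in the authors' deposited table), fell. Reads of these near-identical copies cannot be assigned to one copy with certainty. Ratios also followed transcript length: across genes, which are not independent replicates, the log2 ratio in the group labelled Ph had a Spearman rho of 0.381 with exonic length, and the median exonic length was 916 bp for ribosomal protein genes, 529 bp for histone genes and 2152 bp for all genes. The 72 mitochondrial ribosomal protein genes had a median of -0.10 (percentile 2.87). Of 30 proteasome genes 1 rose, Rpn7 (1.45-fold, q = 0.04 in the authors' deposited table), and 0 passed adjusted over the list alone; the list's median log2 ratio was 0.36 (percentile 98.4).

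The group labelled Sce differed from Mock at fewer genes: 18 rose and 1 fell. Those that rose included Grip at 4.54-fold (q = 0.006), Su(z)2, Psc, the polarity kinase gene aPKC at 1.60-fold (q = 0.018) and the homeobox gene NK7.1 at 2.22-fold (q = 0.018) in the authors' deposited table. Abd-B was the Hox gene that passed, with an authors' mean of 13.7 in Mock and 9393 in the labelled group (q = 0.045 in the authors' deposited table). The other Hox genes had authors' means of 929 (Antp), 774 (Scr), 76.2 (abd-A) and 57.4 (Ubx) in the labelled group, with q-values between 0.218 and 0.292 in the authors' deposited table; adjusted over the list alone, 3 passed. The gene that fell was Adgf-A, an adenosine deaminase growth factor, at 0.385 (q = 0.043) in the authors' deposited table.

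Named after their values were seen, the remaining genes that rose in the group labelled Sce were Best1 (1.58), CG10209 (1.84), CG10479 (6.62), CG31528 (6.67), CG33993 (13.8), CG42666 (1.97), CG5191 (2.499), CG5886 (1.51), CG8398 (2.99), Cyp6v1 (1.67) and Obp85a (9.37), with ratios from the authors' deposited table, and CG1428. The authors' mean of CG1428 was 7.76 in Mock and 6608 in the labelled group (q = 0.045 in the authors' deposited table). By size alone, the highest named genes also held Sce itself, the integrin gene if (4.43, q = 0.058), zfh2 (3.64, q = 0.224), spz (3.07, q = 0.251), Orct2 (2.81, q = 0.121), IP3K1 (2.77, q = 0.197) and daw (2.51, q = 0.299) in the authors' deposited table. The lowest were shf (0.274), fok (0.286), Tom7 (0.286), CBP (0.294), regucalcin (0.323), Adgf-A, the dosage compensation RNA roX2 (0.392), cpx (0.396) and Hsp23 (0.399) in the authors' deposited table; apart from Adgf-A, their q-values were 0.107 or more in the authors' deposited table.

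Of the 27 other developmental regulators 1 rose, NK7.1 (3 higher and 1 lower adjusted over the list alone), although the list's median log2 ratio was 1.81 and lay at percentile 100, under the same condition on what is listed. The 9 segmentation genes and 6 neural precursor genes, with 0 calls, had medians at percentiles 99.58 and 97.54. None of the Wnt, Hedgehog and Dpp, Notch, EGF receptor, JAK-STAT, ecdysone, glial, neuron, hemocyte, immune, muscle, axon guidance, mitosis and proteasome genes passed at q under 0.05 in the authors' deposited table; adjusted over the list alone, 1 Wnt, Hedgehog and Dpp gene and 1 hemocyte gene did. Heat shock and stress genes had a median log2 ratio of -0.34 (percentile 0.02), muscle genes one of -0.50 (percentile 1.96) and axon guidance genes one of -0.06 (percentile 1.99), with 0 calls each in the authors' deposited table. Limited to genes listed by their Mock mean alone, muscle (-0.33, percentile 8.32), axon guidance (14.2) and neural precursor genes (90.2) lay inside the middle 95%. Ribosomal protein genes had a median of -0.41 (percentile 0.0). Copies of histone genes had one of -0.48, but His1 stood at a median ratio of 1.11 and the other 4 types at 0.55 to 0.74. The Spearman rho between log2 ratio and exonic length was 0.373 across genes, and the percentiles of these lists do not take length into account.

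At least 2-fold from Mock were 243 higher and 299 lower genes, without a test. The 19 calls stand beside 882 genes with an unadjusted p under 0.05 (707 higher, 175 lower) in the authors' deposited table, and 10 of the 19 lay at or above the median mean level. Recomputed by the Benjamini-Hochberg method from the p-values as rounded in the authors' deposited table, 0 genes passed. That recomputation differs from the authors' q both in its method and in the decimals of p. With 0.000 taken as 0.0005, a gene could pass only if many others shared that value, so rounding alone can give the 0. The authors' q was a median 0.617 times the Benjamini-Hochberg value. If that factor holds for them, Su(z)2 (q = 0.005) and Grip (q = 0.006 in the authors' deposited table) would pass with unrounded p-values. With the same factor, calls with q of 0.041 or more would not. Among them are Abd-B and Psc (each q = 0.045) and Adgf-A (q = 0.043) in the authors' deposited table. A larger effect of one labelled group than of another was not tested.

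The group labelled Pc again had Hox genes among its largest differences, and all 5 listed ones rose. The authors' mean was 29800 for Scr (listed at the minimum of 1.40 in Mock), 26282 for Abd-B, 7149 for Antp, 744 for abd-A and 284 for Ubx, with q-values of 0.002 or less in the authors' deposited table. Of the 27 other developmental regulators 11 rose and 1, C15, fell (18 and 3 adjusted over the list alone; median log2 ratio 3.23, percentile 100 under the condition given above). The trunk gene tsh rose 15.1-fold and Poxm 41.2-fold, each with q = 0.000 in the authors' deposited table, and dve rose 9.45-fold (q = 0.003 in the authors' deposited table). C15 stood at 0.115 of Mock (q = 0.034) in the authors' deposited table. The T-box gene bi was listed at the minimum of 1.40 in Mock and at 1094 in the labelled group (q = 0.001 in the authors' deposited table). Of 9 segmentation genes cad rose, from an authors' mean of 32.7 to 2971 (q = 0.000 in the authors' deposited table), and 2 passed adjusted over the list alone. The list's median log2 ratio was -0.20 (percentile 38.7), and inv, which rose in the group labelled Ph, had a ratio of 0.87 (q = 0.615) in the authors' deposited table.

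Signalling genes that rose in the group labelled Pc were the Hedgehog receptor gene ptc (3.03-fold, q = 0.005), dpp (authors' means of 96.9 and 1320, q = 0.001), Dad (2.65-fold, q = 0.025) and arm (1.31-fold, q = 0.041) in the authors' deposited table, 4 of the 17 in their list (percentile 78.3). None of 16 Notch pathway genes passed at q under 0.05 in the authors' deposited table (4 adjusted over the list alone; median log2 ratio 0.50, percentile 99.8). Of 15 genes of EGF receptor and FGF signalling rho rose (3.24-fold, q = 0.035 in the authors' deposited table, list percentile 99.0). Of 11 JAK-STAT genes chinmo (authors' means of 71.0 and 2031, q = 0.013) and the cytokine gene upd3 (7.59-fold, q = 0.015) rose in the authors' deposited table, with the list at percentile 63.8.

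Among cell type markers, pros (37.0-fold, q = 0.000) and SoxN (authors' means of 35.0 and 688, q = 0.038) rose again in the authors' deposited table (neural precursor list at percentile 99.8), as did the glial genes axo (12.9-fold, q = 0.005), repo (5.38-fold, q = 0.008) and Nrg (3.66-fold, q = 0.025) in the authors' deposited table (percentile 98.6). Of 13 hemocyte genes the collagen gene vkg (2.55-fold, q = 0.038) and Tig (7.41-fold, q = 0.001) rose in the authors' deposited table, while the hemolectin gene Hml had authors' means of 162 in Mock and 2433 in the labelled group, with q = 0.073 in the authors' deposited table, and the list's median lay at percentile 29.2. The immune regulator pirk rose 7.81-fold (q = 0.009 in the authors' deposited table; list percentile 97.9). Fas2 (3.503-fold, q = 0.023) and the cadherin gene shg (2.74-fold, q = 0.03) rose among axon guidance and adhesion genes in the authors' deposited table (percentile 4.71). The mitotic regulator fzy rose 1.77-fold (q = 0.037 in the authors' deposited table; list median log2 ratio 0.31, percentile 98.0). No neuron, muscle, ecdysone response or proteasome gene passed at q under 0.05 in the authors' deposited table, with lists at percentiles 26.0, 14.7, 6.02 and 43.7. Adjusted over the list alone, the counts of genes that rose were 5 for Wnt, Hedgehog and Dpp, 4 for JAK-STAT, 3 for neural precursors, 4 for glia (and 1 that fell), 4 for hemocytes and 3 for axon guidance.

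After Pc itself, the highest named genes were Grip (13.1, q = 0.000), cher (8.32, q = 0.034), Su(z)2, if (6.33, q = 0.01), repo, rols (5.27, q = 0.003), IP3K1 (4.96, q = 0.002), sev (4.83, q = 0.013) and aPKC (4.82, q = 0.008) in the authors' deposited table. The lowest were C15, shf (0.175, q = 0.113), the ferritin gene Fer2LCH (0.176, q = 0.141), LpR1 (0.209, q = 0.529), the Robo ligand gene sli (0.212, q = 0.174), Tom7 (0.219, q = 0.172) and wun2 (0.245, q = 0.13) in the authors' deposited table. Below these in size came wun (0.262, q = 0.289), vsg (0.281, q = 0.424) and Pde8 (0.287, q = 0.159) in the authors' deposited table.

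In all, 243 genes passed in the group labelled Pc, of which 232 rose and 11 fell; at an unadjusted p under 0.05 the authors' deposited table holds 900 higher and 200 lower. Of the 232, 154 had a Mock mean of at least 798.3. At or above the median mean level 94 rose, with a median ratio of 2.06, and 6 fell. By size alone, 417 genes were at least 2-fold higher than Mock and 401 lower, a balance that turned under other scalings. Ribosomal protein genes had a median log2 ratio of -0.47 with 76 of 86 under 1 (percentile 0.0). The types of histone genes went both ways, with median ratios of 1.24 (His1), 1.07 (His2A), 0.80 (His2B), 0.57 (His3) and 0.68 (His4); 35 of 96 copies lay above 1, and 2 fell (0 adjusted over the list alone). The Spearman rho of log2 ratio with exonic length across genes was 0.314. Heat shock genes (-0.14, percentile 2.19) and DNA replication genes (-0.13, percentile 1.48) had medians under most matched lists, with 0 calls in the authors' deposited table. Limited to genes listed by their Mock mean alone they lay at percentiles 6.32 and 2.60 and immune genes at 88.6, inside the middle 95%, while the 6 muscle genes left had a median of -0.70 (percentile 0.84). This group had 2 libraries.

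Several lists held 0 calls at q under 0.05 in the authors' deposited table for any labelled group. They were the PRC2 and PhoRC list (13 listed), the Trithorax group (16), cohesin (9), RNA interference factors (9), heat shock and stress (22), apoptosis (10), DNA replication (25), germline (12), glycolysis (12) and both classes of ribosomal protein genes. Adjusted over the list alone, AGO2 in the group labelled Pc was the exception among them (2.00, p = 0.004, q = 0.065 in the authors' deposited table). Apart from the values given for ribosomal protein, heat shock and DNA replication genes, the medians of these lists lay within the middle 95% of matched random lists. In the groups labelled Ph, Sce and Pc, 11, 9 and 12 of the 30 lists with listed genes lay outside that range. By chance 1.5 would, but only if genes varied independently and list members differed from other genes in level alone. That does not hold here, so the excess over 1.5 is not a test. Near-identical histone copies count as separate genes, the PRC1 list holds targeted genes, and exonic length was not matched. Limited as above to genes listed by their Mock mean alone, 10, 4 and 8 of 29 lists lay outside the range. Besides Hox genes and the other developmental regulators, the lists that changed sides were those named above and, with Ph, mitochondrial ribosomal proteins (percentile 2.11).

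**Figure D2:**
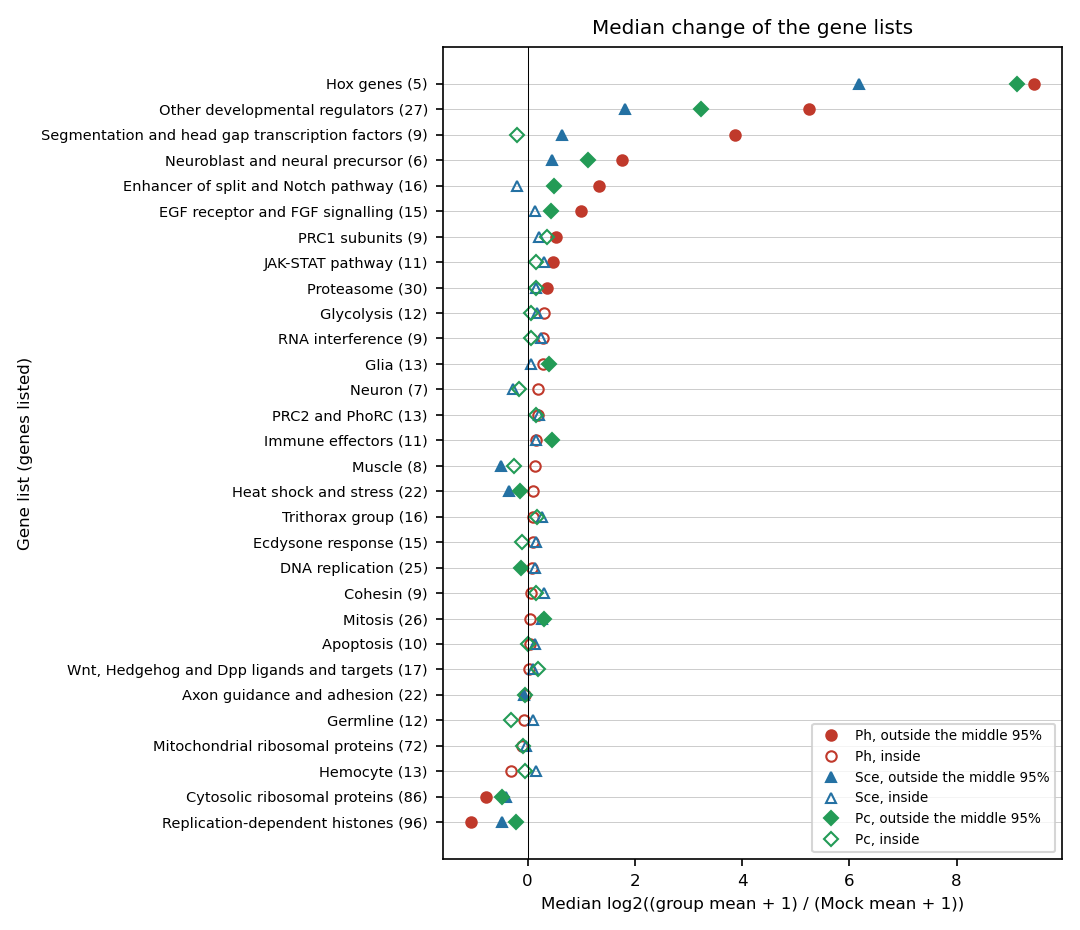
The median log2 ratio of group mean to Mock mean (pseudocount 1) for each gene list, with the number of listed genes in brackets, in the groups labelled Ph (circles), Sce (triangles) and Pc (diamonds). Filled points lie outside the middle 95% of 10000 matched random lists; Hox genes lie highest in each group, and the lowest lists are histone genes with Ph (-1.06), muscle genes with Sce (-0.50) and ribosomal protein genes with Pc (-0.47).

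The labelled groups were also set against one another, which the authors' deposited table does not test, so the following are ratios of group means without a measure of error. Between Ph and Sce, 495 genes were at least 2-fold higher in the group labelled Ph and 332 lower. The 5 highest named genes were Ama (57.3), repo (22.8), sev (17.0), zormin (10.9) and the targeted ph-d (9.23). On the other side stood the targeted Sce (18.7-fold higher in its own group), LpR1 (10.3), GABA-B-R3 (6.55), RpL41 (5.21) and C15 (4.46). Between Ph and Pc, 454 genes were at least 2-fold higher in the group labelled Ph and 410 lower. Highest in Ph were repo (10.0), Argk (7.80), Ama (7.35), ph-p (6.69) and aos (6.44), and highest in Pc were Pc (17.4), RpL41 (7.32), the receptor kinase gene Alk (6.64), GABA-B-R3 (5.34) and GlcAT-P (4.51). Between Sce and Pc, 205 genes were at least 2-fold higher in the group labelled Sce and 358 lower. Highest in Sce were Sce (30.8), LpR1 (9.50), Mrp4 (3.96), Fer2LCH (3.75) and C15 (3.64), and highest in Pc were Pc (20.2), Ama (7.80), kon (6.04), cher (4.63) and Nrg (3.497). Limited to genes at or above the median mean level, the counts were 79 and 104, 73 and 116, and 34 and 38. The balance between higher and lower depends on scaling: after quantile normalization the counts were 417 and 464 for Ph and Sce, 417 and 482 for Ph and Pc, and 247 and 313 for Sce and Pc.

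The last comparison asks how far the responses were shared. The genes Abd-B, aPKC, CG33993, Grip, NK7.1 and Psc rose in all 3 labelled groups. C15, CG14629, CG3192, CG8180, His3:CG33863 and UGP, named after their values were seen, fell in the groups labelled Ph and Pc. Between Ph and Pc 82 genes rose in both, where independent lists of these sizes would share 8.16, and 6 fell in both, against 0.04. Between Sce and Pc 14 of the 18 genes that rose with Sce also rose with Pc, against 0.548, and between Ph and Sce 6 were shared, against 0.633. CG1544 was the gene called in opposite directions, with ratios of 0.544 (Ph, q = 0.024) and 1.48 (Pc, q = 0.033) in the authors' deposited table. Of the 268 genes that rose with Ph, 238 had a ratio above 1 in the group labelled Pc and 214 in Sce. Since these genes were selected against the same Mock mean, a majority above 1 may arise without a shared effect.

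Across genes, which are not independent replicates, the log2 ratios correlated with Pearson's r of 0.526 for Ph and Sce, 0.659 for Ph and Pc and 0.695 for Sce and Pc (Spearman's rho 0.52, 0.52 and 0.672). All 3 comparisons use the same Mock mean, whose chance value they share. At or above the median mean level r was 0.533, 0.587 and 0.72, against 0.337, 0.288 and 0.287 in 100 simulated sets with no effect and a shared control. The share of genes with the same sign was 74.4%, 72.95% and 80.8%, against 61.0%, 59.2% and 59.2% in the simulated sets. Those sets had independent noise of 1 spread for every gene and no trend with exonic length. The log2 ratios of all 3 labelled groups followed length, so both values may be higher than simulated without any effect. The covariance was 0.135, 0.177 and 0.159. The part from the shared Mock is the same quantity in each pair. It is at most the smallest of 3 upper estimates, 0.026, only with an equal spread in all groups and noise independent between genes. That would leave 0.109, 0.151 and 0.133. A trend with length in the Mock mean would enter all 3 covariances but not the differences that gave 0.026. What is left may therefore still hold a part from the shared Mock. Mock libraries could not be divided between the comparisons, so part of the excess in shared calls may come from the shared control.

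**Figure D3:**
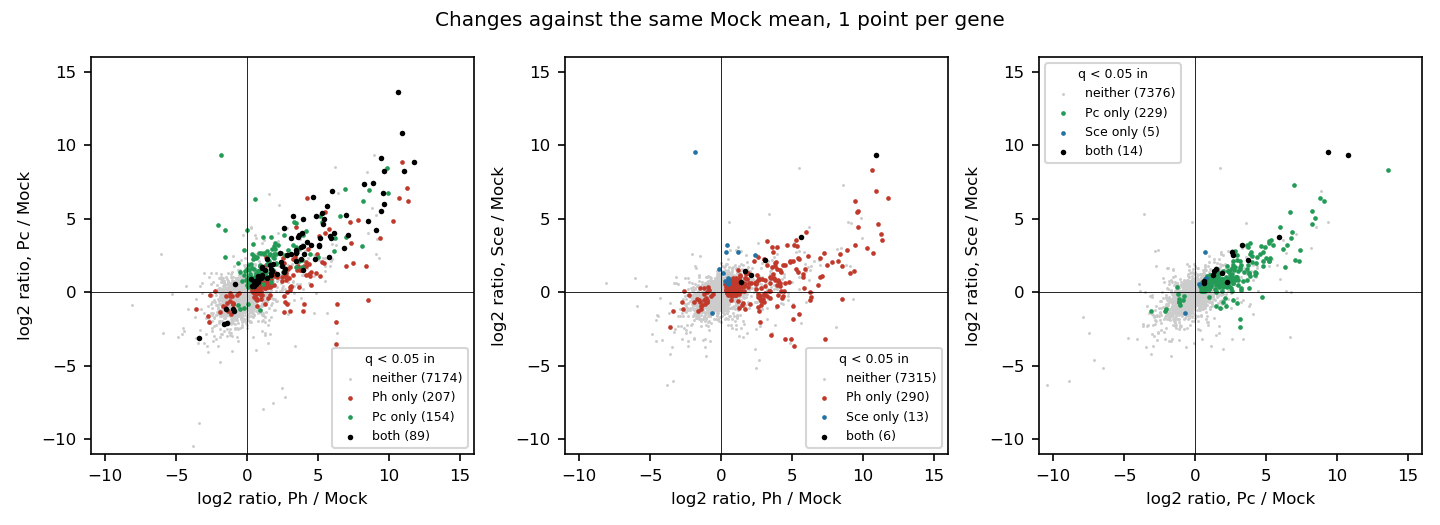
The log2 ratio to Mock of each of 7624 genes in pairs of labelled groups, with genes called at q under 0.05 in the authors' deposited table in colour. Called in both were 89 genes for Ph and Pc (left), 6 for Ph and Sce (middle) and 14 for Pc and Sce (right), most of them higher than Mock in both groups.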

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

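The tests of release by the complex, of the shared Mock and of smaller changes with Sce were chosen only after the result was seen.

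The columns marked nt.gene, which the comparisons above do not use, hold a signal of their own: at q under 0.05 the authors' deposited table calls 189 genes in the group labelled Ph (129 higher and 60 lower) and 9 in the group labelled Sce (5 and 4). What was measured there is not stated in the sources used here. With Ph, 58 genes were higher in both measurements, where independent lists would share 4.54, and 5 were lower in both, against 0.22. The 4.54 leaves out the condition on what is listed, as above. In opposite directions 0 were called. Of the 129 higher genes 123 had a total RNA ratio above 1, and of the 60 lower genes 53 had one under 1 (Pearson's r of 0.511 across genes at or above the median mean level). At or above the median mean level of total RNA, the highest named genes, chosen after their values were seen, were the adhesion gene Ama (147-fold), zfh2 (48.5), the iroquois homeobox gene mirr (18.3), cher (11.5) and sev (10.2), each with q of 0.032 or less in the authors' deposited table. The netrin genes NetA (0.178, q = 0.021) and NetB (0.309, q = 0.034), the Wnt receptor gene fz (0.31, q = 0.017) and Fili (0.198, q = 0.032) were lower in the authors' deposited table. Of the 27 other developmental regulators 11 genes were higher and 0 lower with Ph, and of 22 axon guidance and adhesion genes 1 was higher and 6 lower. Of 16 Notch pathway genes 0 were called with Ph (median 0.09, beside 6 calls and 1.34 in total RNA). Of 15 genes of EGF receptor and FGF signalling 0 were called with Ph (median 0.55, beside 3 calls and 0.99 in total RNA). Heat shock and stress genes had medians of 1.29 (Ph) and 0.70 (Sce), where that of Sce in total RNA was -0.34. These differences were not tested. With Sce, 5 of the 5 higher genes had a total RNA ratio above 1 and 3 of the 4 lower genes one under 1, with r of 0.359.

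The targeted genes stood 8.09-fold (ph-d) to 27.0-fold (Sce) above Mock in their own labelled groups. Release from repression by the complex as a whole is argued against for folds of that size. In the other labelled groups the highest fold of a targeted gene was 1.446, below the lowest fold of Psc and Su(z)2 (2.51). That bound was set after the values were seen, and nothing requires targeted genes to respond as much as Psc and Su(z)2. A small release is not excluded: Sce stood at 1.446 with Ph (p = 0.007, q = 0.071 in the authors' deposited table). Other measures run with the labels: folds of targeted genes in the groups that do not name them lay between 0.876 and 1.45, Hox genes, Psc and Su(z)2 stood higher in all 3 groups, and the nt.gene ratios in the authors' deposited table were 4.87 (ph-p, q = 0.012) and 5.39 (ph-d, q = 0.053) with Ph and 118 (Sce, q = 0.377) with Sce. Reads from the added double-stranded RNA and a feedback of each protein on its own gene stay open; neither was tested, because positions of reads within genes were not used.

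Ribosomal protein genes stood lower in every labelled group, most of all with Ph, and all 5 histone types did with Ph; with Pc, His1 (1.24) and His2A (1.07) stood above Mock, as did His1 with Sce (1.11). For 85 ribosomal protein genes with a length, the median lay under all lists matched on exonic length and level (percentile 0.0; 2.5th percentile of those lists -0.243), which argues against length as the whole cause, although 5 of the genes had no match. For the 5 histone types the median of -0.839 lay at percentile 5.63 of such lists (median -0.379, 2.5th percentile -0.94). Length as the cause is thus not excluded there, but lists of 5 vary widely, so this decides little. For ribosomal protein genes, a chance value of the shared Mock and an effect of each treatment cannot be told apart: the 3 medians differ by up to 0.375 on the log2 scale, but their error is unknown without values per library. In the nt.gene columns the ribosomal protein list had medians of 0.12 (Ph) and 0.14 (Sce), and histone genes had -0.03 and -0.31.

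Fewer genes were called with Sce (19) than with Ph (296), although both groups have 3 libraries. Smaller changes may be the reason, as 88 genes at or above the median mean level differed at least 2-fold from Mock with Sce and 255 with Ph, a ratio of 0.345. A larger spread among the Sce libraries cannot be told apart from an equal one: the spread implied by ratio and p-value, over 3033 genes, had a median of 0.292 with Sce and 0.29 with Ph, a ratio of 1.006, which lies between the bounds set beforehand (at most 1, or above 1.1). This implied spread also holds that of the Mock libraries, which both comparisons share, so a ratio near 1 is partly built in. Working back from a p-value also needs an assumed test, and the authors' test is not given. A difference in how far each protein was lost was not tested. Whether other splits of the libraries call as many genes was not analysed here, because values per library were not used.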

How the results depend on the processing

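Rescaling by the median ratio and quantile normalization kept the direction of all 296, 19 and 243 genes called with Ph, Sce and Pc; the median log2 ratio of all genes moved by less than 0.1, so rescaling could hardly have turned them, and the calls themselves were not recomputed. Pseudocounts of 0.1 and 10 changed no count of 2-fold genes by over 1.5 times. The lowest fold of a targeted gene was 8.088, also with a pseudocount of 0.1, and 7.753 after rescaling. For r between labelled groups, the alternatives were quantile normalization and only genes at or above the median mean level. With the first values included, r lay at 0.436 to 0.533 (Ph and Sce), 0.568 to 0.659 (Ph and Pc) and 0.649 to 0.72 (Sce and Pc). The alternatives at other q-value thresholds, chosen after seeing the data, moved the counts by their construction: by the authors' deposited table, q was under 0.1 for 699 (Ph), 30 (Sce) and 412 (Pc) genes, and under 0.01 for 59 (Ph), 5 (Sce) and 89 (Pc). Benjamini-Hochberg values recomputed from the rounded p-values, also chosen afterwards, gave 209 (Ph), 0 (Sce) and 205 (Pc) genes; for Sce, 882 genes had p under 0.05 in the authors' deposited table. Fewer genes enter when only those at or above the median mean level are kept: 143 (Ph), 10 (Sce) and 100 (Pc) calls were left, and 183 (Ph and Sce), 189 (Ph and Pc) and 72 (Sce and Pc) genes at least 2-fold apart. Quantile normalization left the totals of these direct comparisons near their first values but reversed the balance of Ph against Sce, from 495 higher and 332 lower to 417 and 464, and of Ph against Pc, from 454 and 410 to 417 and 482. Genes at least 2-fold from Mock went from 502 higher and 503 lower to 427 and 607 with Ph, and from 417 and 401 to 370 and 430 with Pc (387 and 444 under rescaling). Of lists outside the middle 95% of random lists, quantile normalization left 11 (Ph, 8 high and 3 low instead of 9 and 2), 8 (Sce, 9 before) and 10 (Pc, 12 before): those lost were proteasome with Ph, neural precursors with Sce, and immune and mitosis genes with Pc, and mitochondrial ribosomal proteins with Ph were gained on the low side. It lowered the median of Hox genes with Ph from 9.44 to 6.97, that of segmentation genes with Ph from 3.86 to 2.43 and that of the other developmental regulators from 5.25 to 4.38 (Ph), 1.81 to 0.98 (Sce) and 3.23 to 1.97 (Pc). Limiting lists to genes listed by their Mock mean alone, chosen after seeing the data, gave 10 (Ph), 4 (Sce) and 8 (Pc) such lists. In the same subset 9 (Ph, 29 before) and 14 (Pc, 34 before) genes that rose lay next to another. Leaving out the targeted genes gave 294, 19 and 243. No paired analysis was possible because the table gives group means and no values per library. For that reason leaving out each replicate, fits of the compared groups alone, library weights, Mock replicates 1 to 3 or 4 to 6 as controls, Mock libraries divided between comparisons, count models and gene set tests were not run; no filter on low values was not run either, since every listed gene passes the one planned. Depth per library is unknown and limits folds of genes with a low mean in Mock, which are given as means.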

Other observations

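Some genes stood higher in the groups labelled Sce and Pc than in Ph. These were chosen after their values were seen, and the difference between groups was not tested. CG1428 was listed at the minimum of 1.48 in the group labelled Ph and at 6608 and 5698 in Sce and Pc (Mock 7.76), as the authors' means. CG10479 had ratios of 1.29 (Ph, q = 0.468), 6.62 (Sce, q = 0.01) and 5.98 (Pc, q = 0.013), and Obp85a, an odorant binding protein gene, 1.32 (q = 0.51), 9.37 (q = 0.018) and 9.82 (q = 0.009) in the authors' deposited table. CG5191 had ratios of 1.11 (Ph, q = 0.434), 2.499 (Sce, q = 0.006) and 3.67 (Pc, q = 0.002), and the Hedgehog receptor gene ptc 1.01 (q = 0.586), 2.19 (q = 0.121) and 3.03 (q = 0.005) in the authors' deposited table. On the other side, Optix had authors' means of 32.4 in Mock, 21557 in Ph, 88.8 in Sce and 430 in Pc. The dosage compensation RNA roX2 had ratios of 0.574 (q = 0.111), 0.392 (q = 0.107) and 0.329 (q = 0.06) in Ph, Sce and Pc in the authors' deposited table.

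Before its test the hypothesis was formed that genes that rise lie next to each other, as Polycomb domains often span neighbouring genes; a further test limited to genes listed by their Mock mean alone was chosen after the result was seen. Of 264 genes that rose with Ph and had a position, 29 were the nearest listed neighbour of another that rose and does not overlap it (27 without the targeted pair ph-p and ph-d). In 10000 random gene sets matched on mean level the median was 15, the upper end of the middle 95% was 26 and the highest was 38. With Pc, 34 of 225 were such neighbours, against a median of 10, an upper end of 21 and a highest of 33. These random sets do not carry the condition that genes without signal in Mock are listed only where a labelled group is high. Among genes listed by their Mock mean alone, and matched on it, 9 of 180 genes with Ph were neighbours (7 without the targeted pair), against a median of 8 and an upper end of 16, and 14 of 150 with Pc, against a median of 4 and an upper end of 12. So whether the genes that rose with Ph cluster cannot be told from these counts. Pairs in both full sets were salr and salm, Scr and Antp, and the noncoding msa beside Abd-B. Signal that reads through from one gene into the next may also give such neighbours, and the 29 genes do not tell this apart.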
